A study of Mus musculus with 9 samples.

How the data were processed

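A total of 9 libraries of As4.1 cells stood behind the data: 2 for each pairing of an antibody (H3K27ac or p300) with a treatment (DMSO or H89) and 1 input. Groups were taken from the antibody and treatment given in the labels. The labels do not say whether replicates were separate cultures. H89 was given at 10 µM at 0, 24 and 48 hours, per the labels' protocols. The study's design also names inhibitors of other proteins and other assays, which were not analysed here.

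The authors deposited 6 peak lists: a consensus list for each antibody and the peaks enriched in DMSO and in H89. The deposited columns used hold positions and other identifiers, and the deposited score is 0 in every row, so no deposited value measures a peak's height or change. MACS2, a peak caller, and DiffBind, which compares peaks between groups, are named per the submitters' processing notes, with the builds GRCm38 and mm10. Their versions, roles, thresholds and normalization, the aligner and the handling of the input are not given in the sources used here. These choices decide which peaks are listed, in which direction and how many, so the numbers of listed peaks depend on steps that could not be varied here. No read count is held in the lists, so the depth of each library is unknown, and the number of p300 calls cannot be compared with that of H3K27ac as a size of effect.

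Positions were read as 0-based starts and are given 1-based. All H3K27ac peaks were 402 bases wide. The p300 peaks were 403 bases wide in the consensus list and 402 in the enriched lists, whose starts lay 1 base higher, so p300 peaks were joined by chromosome and end. The H89-enriched H3K27ac list repeated 8 peaks under a second gene identifier, and each was counted once. All enriched peaks were in the consensus list. The enriched lists carry Ensembl gene identifiers, which the gene table used here does not name.

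Genes came from a RefSeq table of GRCm38.p6. A peak was assigned to the nearest protein-coding gene by its span within 50 kb of the peak centre, with distance 0 inside a gene. This assigned 85.5% of H3K27ac and 81.7% of p300 peaks, and does not show which gene a peak regulates. The table has no strand, so the planned windows around transcription start sites were replaced by windows of 1 kb around both gene ends, which include the 3' ends of genes. The planned motif test was not run because no genome sequence was used here. Ren1 was taken to run forward on chromosome 1, from general knowledge of the gene. How reads shared with the paralog Ren2, or with the Ren2-flanked transgene of the mouse from which this line was derived, were treated is not given in the sources used here.

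Shares have 95% Wilson intervals. Overlap of the antibodies (1 bp or more) and position at gene ends were tested with Fisher's exact test, two-sided. The direction of change and the difference between antibodies in gene-end share were tested with sign-flip permutation tests over chromosomes with 100000 resamples. Chromosomes with at least 10 changed peaks per antibody entered the first test. Those with at least 5 changed peaks in each direction per antibody entered the second. Gene lists were tested with an exact conditional test stratified by the number of consensus peaks per gene (1, 2, 3, 4 to 5, 6 to 9, 10 or more), against all protein-coding genes with a consensus peak, two-sided, with Benjamini-Hochberg adjustment over 68 tests. On simulated lists of 27 genes among the 13050 with an H3K27ac peak, the H89 test called 4.5% of lists with no effect, 94.5% with an odds ratio per peak of 4 and 100% with 10, at an unadjusted threshold of 0.05. The simulation drew genes at random and changed each peak independently, so it does not cover clustered peaks or lists of related genes. The DMSO and p300 list tests were not simulated. Fisher's exact test and the exact conditional test treat peaks or genes as independent, which neighbouring peaks are not, so their smallest p-values are too small.

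The groups, tests, alternatives and 17 gene lists (renin cell, smooth muscle, cAMP and PKA, immediate-early, Notch, matrix and TGF-beta, Rho and YAP, cell cycle, stress, sterol, inflammation, pericyte and stromal, endothelial, tubule, podocyte, leukocyte and housekeeping) were fixed before the data were examined. The rule for named genes was fixed then too: Ren1 first, then per antibody and direction the 8 protein-coding genes with the highest number of enriched peaks in that direction minus the other, then from each list up to 4 members per antibody with the largest such difference. The use of gene ends and gene spans, 4 added alternatives and some tests of explanations were chosen after the files were seen. Alternatives were other assignment windows (10 and 100 kb), other gene-end windows (500 bp and 2.5 kb), an overlap of 50%, merging of peaks within 1 kb, autosomes alone, leaving out chromosomes and Fisher's exact test without strata. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.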

Results

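Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, and the binding of p300, an acetyltransferase that deposits it. The cells were As4.1, a mouse kidney tumour line that expresses the renin gene Ren1. They received 10 µM H89, an inhibitor of protein kinase A (PKA) that also inhibits some other kinases, Rho kinase among them, or the solvent DMSO at 0, 24 and 48 hours. Each antibody had 2 DMSO and 2 H89 libraries, and 1 input library completed the 9. The deposited peak lists hold no read count, fold change, p-value or value per library, so the depth is unknown and no spread between replicates could be computed. A peak is called DMSO-enriched or H89-enriched below where the authors listed it so. Intervals are 95% Wilson intervals for shares and cover counting error only, and peaks and chromosomes are not biological replicates.

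The first question was whether H89 altered the chromatin of Ren1, which encodes renin, the enzyme that starts the renin-angiotensin cascade. At Ren1 (GRCm38 chromosome 1, 133350674 to 133360320), the changed peaks were DMSO-enriched for both antibodies. An H3K27ac peak at 133347555 to 133347956, centred at -2.92 kb from the gene start, was DMSO-enriched. A p300 peak at 133347762 to 133348163, centred at -2.71 kb, overlapped it and was DMSO-enriched as well. Both lie in the upstream flank of Ren1, outside any protein-coding gene, in the region where the classical renin enhancer is found. Within 50 kb of the Ren1 start, 2 of 6 H3K27ac peaks and 1 of 6 p300 peaks were DMSO-enriched, and 0 were H89-enriched. The other DMSO-enriched H3K27ac peak, at 133302316 to 133302717, lay inside the neighbouring gene Plekha6. Within 100 kb, 3 of 10 H3K27ac peaks and 1 of 12 p300 peaks were DMSO-enriched, the additional one lying at 133270043 to 133270444, again inside Plekha6. Both H3K27ac peaks inside Plekha6 overlapped p300 peaks that were in neither list. Inside Ren1 itself, a p300 peak centred at 3.03 kb and an H3K27ac peak centred at 6.08 kb from the gene start were in neither list. No test was run on these few peaks, and their fold changes are not held in the lists. Reads of the near-identical paralog Ren2, or of the Ren2-flanked transgene this line carries, could not be told apart from reads of Ren1 here.

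**Figure D1:**
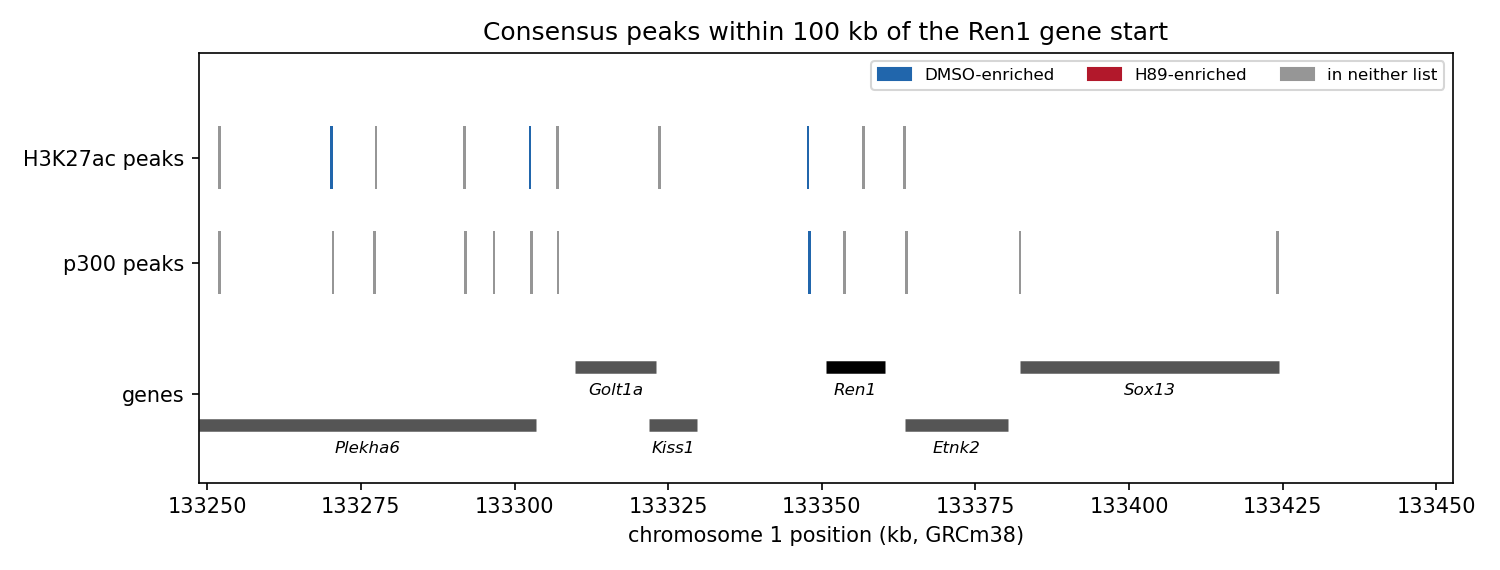
Consensus peaks of H3K27ac and p300 within 100 kb of the Ren1 gene start, drawn to scale against chromosome 1 position in kb (GRCm38), with protein-coding genes below and colour giving the list of each peak. The DMSO-enriched p300 peak overlaps the DMSO-enriched H3K27ac peak nearest to Ren1, the other 2 DMSO-enriched H3K27ac peaks overlap p300 peaks in neither list, and no peak in the window is H89-enriched.

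For H3K27ac across the genome, genes with many H89-enriched peaks included Vps13d, a lipid transfer protein gene, with 14 of 18 peaks, and the transcription factor gene Foxp1, with 14 of 31. Pakap, which encodes an A-kinase anchoring protein, had 14 of 29. Adamts6, Arid5b, Basp1, Dlgap2 and Large1 had 11 H89-enriched peaks each, of 17, 22, 12, 20 and 18. In the other direction, Lrmda had 17 DMSO-enriched peaks of 35, the nuclear regulator gene Aff3 had 15 of 28 and the calcium channel subunit gene Cacna2d3 had 15 of 25. The acid-sensing channel gene Asic2 had 14 of 25, the neighbouring genes Tprg and Trp63 had 13 of 22 and 13 of 20, Trabd2b had 12 of 27, and Rgs3, a regulator of G protein signalling, had 9 of 18. Foxp1 and Pakap each also had 1 DMSO-enriched peak, and Asic2 and Trabd2b each 1 H89-enriched peak. With peaks assigned within 10 kb in place of 50 kb, the excess of 1 direction over the other went from 13 to 8 peaks for Tprg and from 11 to 6 and 7 for Adamts6 and Basp1. Of 47700 H3K27ac peaks, 11032 were H89-enriched (23.1%, 22.8 to 23.5) and 4280 were DMSO-enriched (8.97%, 8.72 to 9.23). H89-enriched peaks thus made up 72.0% of the changed ones, from 63.2% on chromosome 9 to 83.5% on chromosome X. Among 13050 protein-coding genes with an H3K27ac peak, 5096 had H89-enriched peaks without DMSO-enriched ones, 1272 the reverse, 894 both and 5788 neither.

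For p300, Antxr2, an anthrax toxin receptor gene, had 6 H89-enriched peaks of 11, and Basp1 had 6 of 16. Adamts6 had 5 of 18 and Cpe, the gene of carboxypeptidase E, 5 of 12. Dlgap2, the MAP kinase phosphatase gene Dusp4, Ldlrad3 and Me3 had 4 each, of 27, 7, 14 and 24. DMSO-enriched p300 peaks numbered 4 of 15 at the histone deacetylase gene Hdac4, 4 of 14 at Rnf220 and 4 of 27 at Trabd2b. Asic2, the chemokine receptor gene Ccr7, Hhat, Lonrf2 and Tmem270 had 3 each, of 31, 9, 10, 6 and 8. Within 10 kb, the excess was 0 at Dusp4 and Tmem270, 3 at Antxr2 and Adamts6, 2 at Basp1 and 1 at Hhat. Of 55629 p300 peaks, 1227 were H89-enriched (2.21%, 2.09 to 2.33) and 510 DMSO-enriched (0.917%, 0.841 to 0.999), so that H89-enriched peaks made up 70.6% of the changed ones. The DMSO-enriched percent of changed peaks averaged 27.4% ± 4.39 (SD over 20 chromosomes) for H3K27ac and 29.5% ± 10.3 for p300. That difference of -2.08 points did not pass a two-sided sign-flip permutation test over chromosomes (p = 0.316). It was -6.37 points (p = 0.00565, same permutation test) when only peaks over a consensus peak of the other antibody were kept, a filter that by itself lowers the DMSO-enriched share of H3K27ac because it keeps 81.6% of H89-enriched and 48.3% of DMSO-enriched H3K27ac peaks. The filter also lowers this share for p300, though less strongly, dropping 49.0% of DMSO-enriched and 32.4% of H89-enriched p300 peaks. The -6.37 points therefore depend on this unequal overlap and are no separate evidence of a difference in direction.

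Most p300 peaks that changed over an H3K27ac peak lay over H3K27ac enriched in the same condition, as did the one upstream of Ren1. Few changed H3K27ac peaks lay over a changed p300 peak. That share is limited by the number of p300 calls, since 3.12% of p300 and 32.1% of H3K27ac peaks were changed. Depth is unknown, so it does not show that acetylation changed without p300. Of 510 DMSO-enriched p300 peaks, 190 (37.3%) overlapped a DMSO-enriched H3K27ac peak and 1 an H89-enriched one. Among 1227 H89-enriched p300 peaks, 758 (61.8%) overlapped an H89-enriched H3K27ac peak and 0 a DMSO-enriched one. Among p300 peaks over an H3K27ac peak, 73.1% of the DMSO-enriched and 5.95% of the others lay over DMSO-enriched H3K27ac, an odds ratio of 42.9 (32.5 to 56.7, Fisher's exact test, two-sided p = 2.857e-167). For H89 the shares were 91.3% and 26.7%, and the odds ratio was 29.0 (22.7 to 36.9), with a p below what double precision can hold. Of 11032 H89-enriched H3K27ac peaks, 759 (6.88%) overlapped an H89-enriched p300 peak, 8238 (74.7%) p300 in neither list and 2034 (18.4%) no p300 peak. Of 4280 DMSO-enriched H3K27ac peaks, 191 (4.46%) overlapped a DMSO-enriched p300 peak. Another 1875 (43.8%) overlapped p300 in neither list, as did the 2 inside Plekha6, and 2214 (51.7%) overlapped no p300 peak. Peaks were narrow windows of fixed width, so p300 just beside an H3K27ac peak was not counted as overlapping it. At Aff3, for example, DMSO-enriched H3K27ac at 38241303 to 38241704 did not overlap DMSO-enriched p300 at 38241771 to 38242172. At Adamts6, H89-enriched H3K27ac at 104467601 to 104468002 did not overlap H89-enriched p300 at 104468020 to 104468421. The shares without overlap thus do not show that p300 was absent nearby. By gene, Asic2 and Trabd2b were among the 8 leading DMSO-enriched genes of both antibodies, and Adamts6, Basp1 and Dlgap2 among the 8 leading H89-enriched genes of both. DMSO-enriched peaks of both antibodies occurred at 285 genes, against 125.7 expected from the number of H3K27ac peaks per gene (p = 2.954e-86, exact conditional test), and H89-enriched peaks of both at 640, against 431 expected (p = 6.054e-93, same test). The number of p300 peaks per gene was not accounted for. These genes include those of the overlapping peaks counted above, so they are no separate support. Both antibodies were compared in cells given the same treatment, and the lists do not say whether the libraries came from the same cultures.

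**Figure D2:**
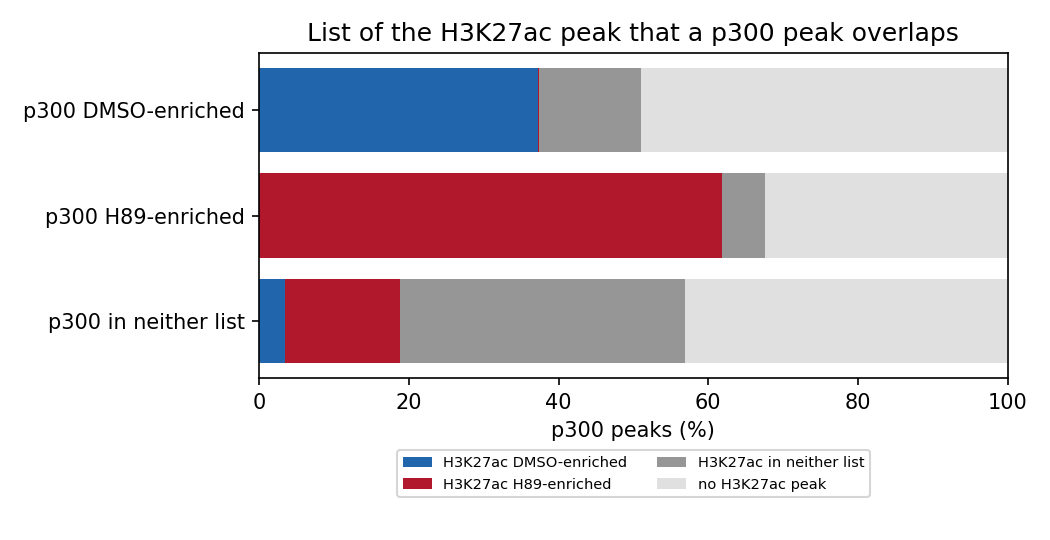
Percent of p300 peaks in each list (rows) that overlap, by 1 bp or more, an H3K27ac peak of each list (colours) or none. Of the DMSO-enriched p300 peaks 37.3% lie over DMSO-enriched H3K27ac, and of the H89-enriched ones 61.8% lie over H89-enriched H3K27ac.

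The position of changed peaks relative to genes was compared next, using both ends of each protein-coding gene because strand was not given. Counts per gene list were made after the genome-wide shares had been seen, and the lists named here were picked for their values. H3K27ac at the gene ends of the housekeeping list, which holds Actb, Eef1a1, Emc7 and Polr2a, was H89-enriched in 15 of 24 peaks, and at those of the stress list, which holds Trib3, Chac1 and Gadd45a, in 14 of 19. The gene ends of the matrix and TGF-beta list, which holds Col6a1, Tgfbr2 and Col5a1, gave 4 of 28. Rho and YAP genes gave 14 of 22, cell cycle genes 15 of 28 and cAMP and PKA genes 8 of 28, against 32.3% of the 9436 gene-end peaks outside the housekeeping list. Genes named here are list members whose changed peaks need not lie at gene ends, and those of Actb, Col6a1 and Col5a1 all lay elsewhere. Across the genome 27.8% of H89-enriched, 4.23% of DMSO-enriched and 19.2% of other H3K27ac peaks lay within 1 kb of a gene end. The odds ratio of DMSO-enriched to H89-enriched was 0.115 (0.0984 to 0.134, Fisher's exact test, two-sided p = 2.323e-280). For p300, 2.12% of H89-enriched (26 of 1227), 4.31% of DMSO-enriched (22 of 510) and 18.7% of other peaks lay at a gene end, so changed p300 peaks were mostly away from gene ends. The DMSO to H89 odds ratio of p300 was 2.08 (1.17 to 3.71, Fisher's exact p = 0.0152), and it did not pass with windows of 500 bp (1.55, p = 0.201) or 2.5 kb (1.19, p = 0.400). The H89 minus DMSO difference in gene-end share was larger for H3K27ac than for p300 by 26.1 points (SD 7.36 over 20 chromosomes). The permutation p was 1e-05, the smallest that 100000 sign flips can give.

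**Figure D3:**
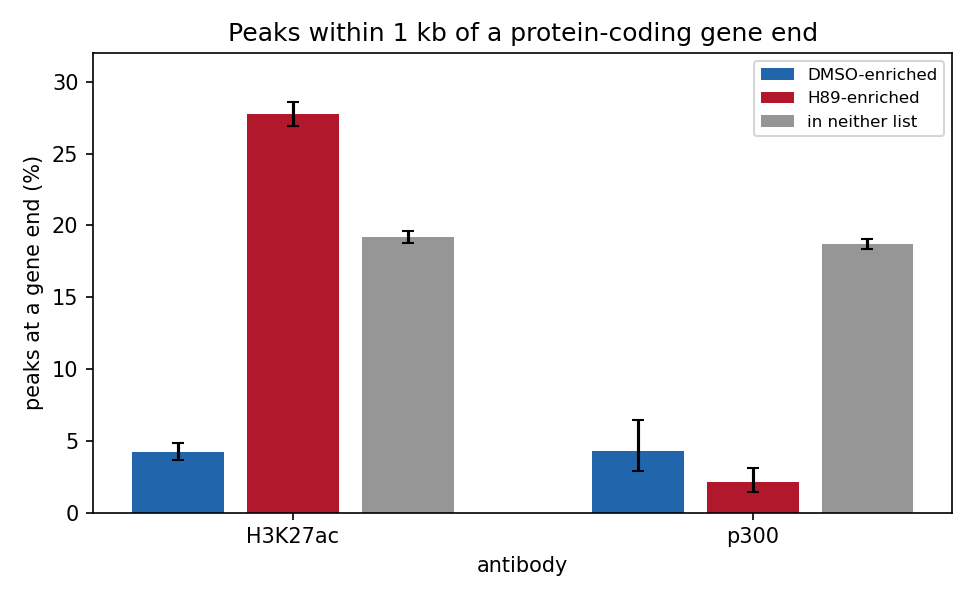
Percent of peaks within 1 kb of either end of a protein-coding gene, by antibody and list, with 95% Wilson intervals. Among H3K27ac peaks the H89-enriched bar (27.8%) is the highest and the DMSO-enriched bar (4.23%) the lowest, while both changed groups of p300 lie below 5%.

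Of 17 gene lists, tested for each antibody and direction, integrated stress, oxidative stress and apoptosis genes had more members with H89-enriched H3K27ac than expected. Of 25 such genes with an H3K27ac peak, 23 had an H89-enriched one, against 12.6 expected from the number of peaks per gene (odds ratio 13.9, exact conditional test, Benjamini-Hochberg adjusted p = 0.000474 over 68 tests). Trib3, a pseudokinase gene induced by amino acid stress, had 3 of 3 peaks H89-enriched, the glutathione-degrading enzyme gene Chac1 had 2 of 3, the anti-apoptotic gene Bcl2l1 had 4 of 10 and the growth arrest gene Gadd45a 4 of 9. Within 10 kb the count of Gadd45a was 2. Xbp1 and Srxn1, named after their values were seen, were the members with peaks but no H89-enriched one. Atf4, Ddit3 and Gadd45b, likewise named afterwards, had no assigned peak and did not enter the test. Ddit4 and Txnrd1, also named afterwards, each had 1 DMSO-enriched peak beside 1 H89-enriched peak. The list mixes genes that promote survival, such as Bcl2l1 and Mcl1, with genes that promote death, such as Bbc3 and Pmaip1. No other test of the 68 passed after adjustment, and 5 passed before it, this one included. Over the alternatives the adjusted p of the stress list ranged from 0.000119 to 0.0017. At gene ends, 14 of 19 stress peaks (51.2 to 88.2%), 15 of 24 housekeeping peaks (42.7 to 78.8%) and 14 of 22 Rho and YAP peaks (43.0 to 80.3%) were H89-enriched. These intervals overlap, so H89 enrichment at gene ends is not shown to be particular to stress genes. In an added alternative with strata also by presence of a gene-end peak, 12.7 stress genes were expected (adjusted p = 0.000469, exact conditional test). The Rho and YAP and the housekeeping lists did not pass there (adjusted p = 0.185 each, same test). Lists were not tested against each other, so the list result is not shown to be particular to stress genes either.

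The lists nearest to the study's question did not pass. Among genes that mark or maintain renin cells, 12 of 18 had H89-enriched H3K27ac (9.56 expected, adjusted p = 0.833, exact conditional test) and 3 had DMSO-enriched H3K27ac (4.34 expected, adjusted p = 0.886). Rbpj, the effector of Notch signalling, had 6 of 12 peaks H89-enriched, the integrin gene Itgb1 4 of 7 and the proteoglycan gene Cspg4 3 of 6, while Pbx1 had 6 of 33 DMSO-enriched and 1 H89-enriched. For cAMP and PKA components, 20 of 32 genes had H89-enriched peaks (20.9 expected) and 7 had DMSO-enriched peaks (11.5 expected), with Pde4b at 6 of 20 H89-enriched, Akap13 at 5 of 18 with 1 DMSO-enriched, and the adenylyl cyclase gene Adcy5 at 3 of 9 DMSO-enriched. Immediate-early genes, many of them targets of CREB or SRF, had H89-enriched peaks at 17 of 28 (15.0 expected) and DMSO-enriched at 3 (6.58 expected). Among them Klf6 had 6 of 6 peaks H89-enriched, Klf4 6 of 7, Cebpb 4 of 4 and Atf3 3 of 6. Notch genes gave 9 of 17 H89-enriched (9.79 expected) and 4 DMSO-enriched (4.79 expected), with Maml3 at 7 of 15 H89-enriched and Notch3 at 2 of 3 DMSO-enriched. Many of these peaks lay farther out, and within 10 kb the excess was 3 for Rbpj and Klf4, 2 for Cebpb, and 1 for Itgb1, Klf6, Atf3 and Notch3.

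Contractile and matrix genes went both ways. Smooth muscle genes had H89-enriched H3K27ac at 9 of 19 (10.5 expected) and DMSO-enriched at 6 (4.78 expected). Acta2, smooth muscle actin, had 3 of 5 peaks H89-enriched, Vcl 4 of 14 and Cald1 7 of 16 with 1 DMSO-enriched, whereas the myosin light chain kinase gene Mylk had 4 of 8 DMSO-enriched. Matrix and TGF-beta genes had DMSO-enriched peaks at 17 of 34 (12.8 expected, adjusted p = 0.619, exact conditional test) and H89-enriched at 18 (22.7 expected). Col6a1 had 6 of 9 peaks DMSO-enriched, the TGF-beta receptor gene Tgfbr2 6 of 12, Col5a1 6 of 15 with 1 H89-enriched, and Col8a1 7 of 12 H89-enriched. Rho, actin and YAP genes had H89-enriched peaks at 22 of 25 (16.0 expected, p = 0.00764, adjusted p = 0.173, exact conditional test) and DMSO-enriched at 5 (8.58 expected), with Actb at 4 of 4, Wwtr1 at 7 of 10, and Amotl1 and Mrtfb at 8 of 16 each. Housekeeping genes had H89-enriched peaks at 18 of 26 (10.8 expected, adjusted p = 0.111, exact conditional test) and DMSO-enriched at 2 (3.25 expected). Within 10 kb the excess was 3 for Cald1, Col6a1 and Col5a1, 5 for Mrtfb and 2 for Actb. With assignment within 10 kb, the Rho and housekeeping lists passed (adjusted p = 0.0288 and 0.0297, exact conditional test), and over all alternatives their adjusted p ranged from 0.000436 to 0.319 and from 0.0297 to 0.198. The matrix list passed for DMSO when peaks per gene were not accounted for (adjusted p = 0.000236, Fisher's exact test), and over its alternatives the adjusted p reached 0.718.

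Cell cycle genes had H89-enriched H3K27ac at 20 of 31 (14.4 expected, adjusted p = 0.537, exact conditional test) and DMSO-enriched at 3 (5.01 expected), the cyclin gene Ccnd2 at 2 of 3 and the inhibitor gene Cdkn1a at 2 of 4 H89-enriched. Sterol genes gave 13 of 19 (9.33 expected) and 3 (3.63 expected), with Insig1, a brake on sterol synthesis, at 3 of 3 H89-enriched and Cyp51 at 2 of 2. Inflammation genes gave 12 of 22 (12.6 expected) and 8 (6.05 expected). There the prostaglandin synthase gene Ptgs2 had 4 of 10 H89-enriched, and the chemokine gene Cxcl12 had 4 of 7 DMSO-enriched. All 4 Ptgs2 peaks and 3 of the 4 Cxcl12 peaks lay over 10 kb from the gene, so that within 10 kb the counts were 0 and 1, while Cdkn1a, Insig1 and Cyp51 had 1 each. Of the marker lists of other cell types, pericyte and stromal genes had H89-enriched peaks at 13 of 21 (10.9 expected) and DMSO-enriched at 3 (4.68 expected), endothelial genes at 6 of 11 (6.63) and 4 (3.22), and kidney tubule genes at 8 of 14 (7.30) and 2 (3.29). Podocyte genes gave 5 of 9 (4.65 expected) and 3 (2.05 expected). Leukocyte genes, of which 7 had a peak, gave 3 (2.78 expected) and 3 (0.735 expected, adjusted p = 0.352, exact conditional test). Meis1 at 5 of 13, Ptprb at 3 of 5, the endocytic receptor gene Cubn at 7 of 14 and Itgam at 3 of 5 were H89-enriched, and Egfl7 at 1 of 4 and Synpo at 2 of 6 DMSO-enriched, of which Egfl7 had 0 within 10 kb.

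For p300 few list members had a changed peak, and no list passed adjustment in either direction with peaks per gene accounted for. H89-enriched p300 peaks occurred at 5 of 34 cAMP and PKA genes (3.53 expected), among them Pakap with 3 of 45, and at 4 of 25 stress genes (1.71 expected), among them Bcl2l11 with 2 of 3. They occurred at 3 of 24 Rho and YAP genes (3.58 expected), with Ccn2 at 2 of 7, and at 3 of 14 tubule genes (1.10 expected), with Cubn at 3 of 21. Matrix genes had DMSO-enriched p300 peaks at 5 of 34 (3.01 expected), Col1a1 and Col6a1 with 1 each (adjusted p = 0.766, exact conditional test, and 0.031 by Fisher's exact test without strata), and H89-enriched at 3 (5.50 expected), Lox with 2 of 7. DMSO-enriched p300 occurred at 2 of 19 renin cell genes (0.919 expected), which were Ren1 and Pbx1, and H89-enriched at 1, which was Rgs5. At immediate-early genes there were 2 of 28 with DMSO-enriched p300 (1.12 expected), Fosl2 and Sik1, and 2 with H89-enriched (2.28 expected), Klf4 and Klf6. Cxcl12 had 3 DMSO-enriched p300 peaks and 1 H89-enriched of 13, and its balance turned to 1 more H89-enriched when peaks were assigned within 10 kb. DMSO-enriched p300 peaks occurred at 3 cAMP and PKA genes (1.87 expected), 2 stress genes (0.856), 1 tubule gene (0.580) and 0 Rho and YAP genes (1.95). Inflammation genes had DMSO-enriched p300 at 3 of 22 (1.42 expected) and H89-enriched at 4 (2.61), and Notch genes at 0 of 18 (0.947) and 3 (1.78), with Maml2 at 2 of 27. Sterol genes gave 1 of 19 (0.436 expected) and 2 (0.849), pericyte and stromal genes 0 of 21 (0.965) and 2 (1.84), and cell cycle genes 1 of 31 (0.782), which was E2f7, and 1 (1.63), which was Rb1. Smooth muscle genes gave 1 of 20 (1.11 expected), Mylk, and 1 (2.0), Cald1. Endothelial genes gave 1 of 13 (0.498 expected), Egfl7, and 1 (0.994), Emcn, podocyte genes 1 of 9 (0.559), Synpo, and 0 (1.02), leukocyte genes 0 of 5 (0.0746) and 1 (0.149), Itgam, and housekeeping genes 0 of 26 (0.466) and 1 (0.985), Emc7. Within 10 kb the excess of p300 peaks was 0 for Bcl2l11, Lox, Col6a1, Pbx1, Fosl2, Sik1, Klf4, Klf6, E2f7, Egfl7, Emcn and Emc7, and 1 for Ccn2.

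**Figure D4:**
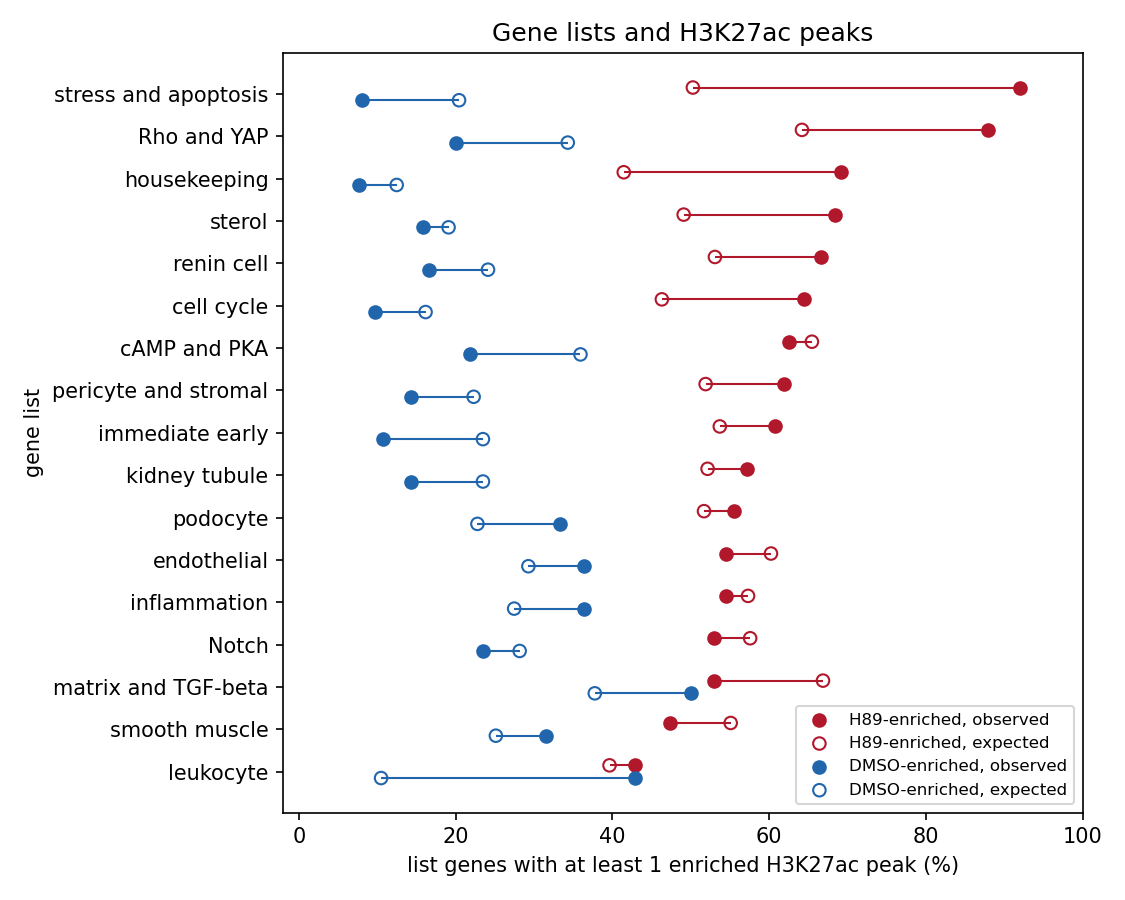
Percent of genes of each list, among those with an H3K27ac peak, that had at least 1 H89-enriched (red) or DMSO-enriched (blue) H3K27ac peak, observed (filled) and expected from the number of peaks per gene (open). The stress list lies farthest above its expected value for H89, with 23 of 25 genes, and is the one list that passed adjustment.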

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

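Both tests of explanations here were chosen after the result was seen. The H89 minus DMSO difference in the share of changed peaks at gene ends differed between the antibodies by 26.1 points, being 23.4 points for H3K27ac (above 0 on 20 of 20 chromosomes) and -2.71 points for p300 (below 0 on 12 of 20). It stands out because the difference itself passed a permutation test over chromosomes (p = 1e-05, the smallest it can give). The p300 side rests on few gene-end peaks, 22 DMSO-enriched and 26 H89-enriched over all chromosomes, so its values per chromosome are uncertain. For p300 alone, the gene-end odds ratio of DMSO to H89 was 2.08 (Fisher's exact p = 0.0152) but did not pass with windows of 500 bp or 2.5 kb. A gain of some chromosomes during treatment was taken to leave others with more DMSO-enriched gene-end peaks. Even on the lowest, chromosome 4, 91.04% of changed H3K27ac gene-end peaks were H89-enriched, so the excess was not confined to some chromosomes. That prediction depends on the normalization, which is not given. H89-enriched peaks also made up at least 63.2% of all changed H3K27ac peaks on every chromosome, so this test cannot decide on copy number. A general rise at gene ends, for example from the authors' normalization or from unequal enrichment of the libraries, predicts that housekeeping genes take part. Of their gene-end peaks 62.5% (15 of 24, 42.7 to 78.8) were H89-enriched, against 32.3% of 9436 others. Gene-end peaks of the matrix and TGF-beta list were H89-enriched less often, at 14.3% (4 of 28, 5.70 to 31.5). A rise alike at all gene ends is thus not shown, although 1 of 17 lists, picked for its low value, does not exclude a general shift. A technical shift at gene ends may contribute and stays open, as does an effect of H89 itself.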

How the results depend on the processing

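Of 859 alternatives over 225 results, most were counted as unchanged. For tests, this count includes changes of direction where neither value passed the threshold. For example, renin cell genes with H89-enriched H3K27ac went from 12 (9.56 expected) to 8 (8.66 expected) with the nearest gene end. Within 10 kb, smooth muscle genes with DMSO-enriched H3K27ac went from 6 (4.78 expected) to 3 (3.86 expected). Tubule genes with H89-enriched H3K27ac went from 8 (7.30 expected) to 5 (5.82 expected) there. The direction difference between antibodies was -6.37 points and passed (p = 0.00565, permutation test) with peaks over a consensus peak of the other antibody. That filter drops 51.7% of DMSO-enriched and 18.4% of H89-enriched H3K27ac peaks, and 49.0% and 32.4% of p300 peaks. The pass therefore depends on this unequal overlap and is no separate evidence. The p300 gene-end odds ratio of DMSO to H89 no longer passed at 500 bp (1.55) or 2.5 kb (1.19). The number of list tests past adjustment, 1 in the report, was 3 with assignment within 10 kb and 4 with Fisher's exact test without strata, which ignores that genes with many peaks hold a changed one more often. The stress list passed in each alternative run. Cxcl12 p300 turned from -2 to 1 (H89-enriched minus DMSO-enriched peaks) within 10 kb. Apart from the strata and the filter on overlap, the cause was not tested. Of 140 values of named genes, 84 stayed within 1.5 times at 10 kb and 25 fell to 0. At 100 kb 129 stayed and 1 was 0, and with the nearest gene end 103 stayed and 11 were 0, the last added after seeing the data. The overlap odds ratios ranged from 39.9 to 45.7 (DMSO) and 28.1 to 30.6 (H89) when each chromosome was left out. No paired analysis was possible because the deposited lists hold no value per replicate. For the same reason leaving out replicates and a stricter threshold were not run, nor were the motif alternatives. Counting bases or wide peaks moved nothing, since peaks of an antibody share 1 width. Depth is unknown, so whether fewer p300 calls reflect weaker libraries cannot be judged.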

Other observations

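Both tests in this part were set before their results were seen, on patterns found in the same data. Changed H3K27ac peaks formed, in some places, long runs without an unchanged consensus peak between them. A DMSO-enriched run of 16 peaks spanned 274.9 kb in and beside Lrmda (chromosome 14, 22823353 to 23098290), and others of 9 and 7 peaks lay at Asic2 and Aff3. An H89-enriched run of 12 peaks spanned 334.6 kb near Ccnl1, Veph1 and Ptx3 (chromosome 3, 65958300 to 66292886). Another of 12 peaks, near Abraxas1, Gpat3 and Wdfy3 on chromosome 5, spanned 1027.4 kb. A run of 10 on chromosome 2, with no assigned gene within 50 kb, spanned 966.6 kb. A run therefore need not be a compact block. Runs of 9 lay near Klf6, near Vps13d and Dhrs3, and near Fas, a death receptor gene, and Ch25h, which encodes cholesterol 25-hydroxylase. For p300, the longest H89-enriched run held 5 peaks near Klf12. There were 3 runs of 4 peaks, at 34760513 to 34773029 on chromosome 8, all over 20 kb from its nearest gene Dusp4, at 34610179 to 34617943 on chromosome 8 and at 34378930 to 34393136 on chromosome 19, the last pair with no assigned gene within 50 kb. These genes were taken from the longest runs after the values were seen, and no test of run length was made.

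H89-enriched H3K27ac peaks overlapped a p300 consensus peak more often (81.6% of 11032) than DMSO-enriched ones (48.3% of 4280), with 63.9% for peaks in neither list. Location at gene ends would remove this difference among other peaks, yet away from gene ends it was 30.01 points (28.2 to 31.8), above 0 on 20 of 20 chromosomes. One hypothesis is that H89-enriched acetylation may arise mainly at sites p300 already occupies, but how the consensus was formed is not given in the sources used here and it may hold peaks of H89 libraries, so prior occupancy was not tested. Peak strength, which could link both calls, also stays open. Overlap was counted between narrow windows of fixed width, so p300 just beside an H3K27ac peak was missed. The difference is therefore one of overlap, and is not shown to be one of p300 nearby.

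Peaks of both antibodies were enriched in the same condition at 948 p300 sites. A local copy-number difference between cultures could produce this, and would change neighbouring H3K27ac peaks too. Of 1513 neighbours within 20 kb, 43.95% (41.5 to 46.5) were in the same list and 2.58% in the opposite list. The share was 35.0% (30.3 to 40.0) at DMSO-enriched sites and 46.9% (44.0 to 49.8) at H89-enriched sites, against 8.97% and 23.1% of all H3K27ac peaks. By a rule set beforehand, an upper bound below 50% was to count against copy number, and the upper bound of 46.5% met it. That verdict was not kept. Without values per peak the share that a copy-number change would bring into a list is unknown, and neighbours shared the direction more often than peaks at large. Local copy number therefore cannot be told apart from regional changes in chromatin, and neither was excluded.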
